A study of Homo sapiens with 6 samples.

How the data were processed

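The data are 6 arrays of BEAS-2B, a virus-transformed human bronchial epithelial cell line: 3 from vehicle-treated control cultures and 3 from cultures given TNF-a and IL-4 together, 50 ng/ml per cytokine, during 18 h. Per the labels' protocols, cytoplasmic RNA was extracted, biotin-labelled and detected with streptavidin-Cy3 on Illumina BeadChips. The description of control replicate 1 speaks of a cytokine treatment after seeding, against its title, source and treatment entry, and the array was kept as a control. Its CCL26 and CXCL8 levels were 7.87 and 5.09, where the lowest on a TNF-a/IL-4 array were 13.03 and 10.82. The series describes biological triplicates, and nothing in the labels says whether the 3 cultures of a group were grown on separate days.

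Per the file headers and the submitters' processing notes, the signals come from BeadStudio 3. The deposited table gives for each of 48701 probes the mean bead intensity on a linear scale, the number of beads, the standard error over the beads and a detection p-value, which ranks the probe against the array's negative control beads. The intensities were neither background-subtracted nor normalized, as their values show. A second table holds the authors' processed intensity for the same probes. Its scale is linear, its median is 7.44 on each of the 6 arrays, and values below 0 occur. Each array's processed values ranked its probes as the unprocessed signals did (rank correlation 1), and on control replicate 1 they were the unprocessed signal less a constant. The method behind them is not given in the sources used here, and they served only as an alternative. For that, values under 16 were set to 16 and log2 was taken. The median of 7.44 lies below this floor, so most of the 48701 values of each array became the same constant. The counts from them are therefore not those of the authors' processing as it stands.

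The intensities were corrected for background and normalized with the neqc function of limma 3.58.1 in R 4.3.3. Its negative-control parameters were inferred from the detection p-values, an offset of 16 was added, arrays were quantile normalized and values were taken to log2. The offset pulls log2 changes of dim probes towards 0. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were tested, which left 14659. Quantile normalization sets the distributions of all arrays equal, so a change of total mRNA in the treated cells would not be seen.

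Probe names came from the platform annotation in which 24782 probes carry 1 gene symbol, none carries several, and 23919 of the array's probes are not listed and stay unnamed here. Entrez IDs of 24154 of the listed probes were found in the RefSeq table of the assembly GRCh38.p14, used only for names, and 0 symbols changed. Of the tested probes, 12151 had a name, 2508 had none, and the named ones stood for 10967 genes. No position on the genome is given, because no build is named for the probes. Each gene was read from its tested probe with the highest mean signal. Among the called genes, 245 had no other tested probe, 2 had others with the same call and 22 had another tested probe that did not pass. Whether probes separate close paralogs, such as those of the metallothionein, AKR1C and beta-defensin families, was not tested.

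The difference TNF-a/IL-4 minus control was fitted per probe with limma's lmFit and eBayes without a block, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested probes. A probe was called at an adjusted p under 0.05, and the count with at least a 1.5-fold change was taken beside it. Of 28 gene lists, the 27 with measured members were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and the members past the threshold were counted over all genes and adjusted over the list alone. The groups, the tests, the lists, the rule for naming genes and most of the settings listed last were fixed before the data were examined. The rule named the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap and that were detected on all 3 arrays of the higher group. It also named up to 4 called members of each list with the largest change, the 2 measured members with the largest change where fewer than 2 passed, and 20 genes fixed in advance where measured. Uncharacterised LOC and clone names took no place among the largest changes. GADD45B and SNAI1 are named besides, chosen after their values were seen, as are the genes of the 4 lists added later.

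Where a gene was not detected on any of the 3 arrays of a group, its change is given as a bound. The bound sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the gene's own value and the lowest normalized value among detected probes of that array. All changes are means of 3 arrays against 3, and the number of arrays limits their precision.

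Each of 3 chips held the control and the TNF-a/IL-4 array of the same replicate number, with the control always in position E and the treated sample always in position F, so position and treatment cannot be told apart. Arrays of the same chip deviated together from their group means, with correlations over probes of 0.64, 0.56 and 0.47, all above the limit of 0.1 set for pairing. Probes are not independent replicates, and the correlations describe these arrays. The replicate number and the chip name the same block, and the fit with that block leaves each log2 change as it is and changes its error. Its result is given for named genes and lists where it changes a call or moves a count by more than 1.5-fold, and called lists have their medians within each chip beside them.

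The fits were tested on simulated data with the spread and chip deviations of these arrays, in which 200 of 14659 probes were changed. Without the block, 19.4% of the changes of 1 log2 unit, 97.0% of those of 2 units and 100% of those of 3 units were recovered, with 0 false calls. With the block, 98.5%, 100% and 100% were recovered, with 16 false calls among 215. In a simulation of 25 lists over 10967 genes, all 5 lists shifted by 0.8 log2 units and 0 of the others were called. Those lists held random genes with noise drawn independently. The simulation therefore does not show how the preset correlation performs on smaller shifts or on lists whose members vary together.

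The alternatives covered background correction, offset, between-array normalization, the authors' values, the detection filter, the spread model, array weights, the block, the choice of probe, the list test and leaving out each array. Leaving out both arrays of a chip, and the block combined with median scaling, with the authors' values or with an estimated list correlation, were added after seeing the data.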

Results

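Steady-state mRNA was measured with Illumina BeadChips in BEAS-2B bronchial epithelial cells, 3 control arrays and 3 arrays of cells given TNF-a and IL-4 together. TNF-a is an inflammatory cytokine that activates NF-kB, and IL-4 is a type 2 cytokine that signals through STAT6. The mean unprocessed signal was 481, 379 and 333 on control arrays 1, 2 and 3 and 411, 349 and 301 on the TNF-a/IL-4 arrays of the same chips. Detection at p under 0.05 reached 15472, 15019 and 14405 probes on the control arrays and 14646, 14745 and 12848 on the treated arrays. A probe was averaged over about 40 beads on every array, from 40.3 to 40.9. Below, an error after a log2 change is its SE from 3 arrays against 3, and an error after a level is the SD over 3 arrays.

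The comparison asked which mRNAs differ between resting cells and cells activated by TNF-a and IL-4. The largest rises were those of secreted inflammatory proteins. CXCL8, the neutrophil chemoattractant interleukin-8, rose by 5.07 ± 0.54 on the log2 scale (33.7-fold, adjusted p = 0.00452), from a level of 6.28 ± 1.26 to 11.36 ± 0.47. The monocyte chemoattractant CCL2 rose by 4.79 ± 0.49 (27.6-fold, adjusted p = 0.00379), and CCL26, the eosinophil chemoattractant eotaxin-3, rose by 4.78 ± 0.67 (27.4-fold). The cytokine IL32 rose by 4.10 ± 0.56 (17.2-fold, adjusted p = 0.00853).

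Other genes among the 12 largest rises were PPFIBP2, a liprin family member, at 3.95 ± 0.31, the hyaluronan-binding protein TNFAIP6 at 3.45 ± 0.34, and the leukocyte adhesion receptor ICAM1 at 3.37 ± 0.41. C1QTNF1 rose by 3.25 ± 0.24, the NF-kB inhibitor TNFAIP3 by 3.21 ± 0.30, the ubiquitin-like UBD by 3.13 ± 0.30, complement C3 by 3.10 ± 0.55 and the cytokine IL6 by 2.99 ± 0.55, with adjusted p from 0.00244 for PPFIBP2 and C1QTNF1 to 0.0296 for IL6. The size of the rises differed between chips. CXCL8 differed by 6.54, 5.47 and 3.21 on chips 1, 2 and 3, CCL26 by 5.79, 5.91 and 2.62, CCL2 by 6.38, 3.36 and 4.62, and IL32 by 4.65, 5.15 and 2.50. CXCL8, IL32, PPFIBP2, TNFAIP6, C1QTNF1, UBD and C3 were detected on 2 of the 3 control arrays. The rise of C3 and that of IL6 each missed the threshold in 4 of the 6 fits that left out a single array.

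The 12 largest falls were smaller. The thyroid hormone deiodinase DIO2 fell by 2.65 ± 0.34 on the log2 scale (6.28-fold lower, adjusted p = 0.00767), the retinaldehyde reductase DHRS3 fell by 2.57 ± 0.44 (5.95-fold lower, adjusted p = 0.0217), and the matricellular protein CCN5 fell by 2.42 ± 0.30 (5.37-fold lower, adjusted p = 0.00734). IGFBP3, which binds insulin-like growth factors, fell by 2.20 ± 0.33, the GDNF family receptor GFRA2 fell by 2.07 ± 0.31, and the retinoic acid binding protein CRABP2 fell by 2.06 ± 0.38. RIPOR2, not detected on any treated array, was at least 2.56-fold lower (adjusted p = 0.00277). ID1, a helix-loop-helix protein induced by BMP signalling, fell by 1.99 ± 0.26, the sulfatase SULF2 fell by 1.95 ± 0.17, the thrombin receptor F2R fell by 1.88 ± 0.22, CCDC80 fell by 1.87 ± 0.20 and SMAD6, an inhibitor of BMP signalling, fell by 1.84 ± 0.21. CRABP2 missed the threshold in 5 of the 6 fits without a single array, DHRS3 in 3, IGFBP3 in 2 and GFRA2 in 1. DIO2, GFRA2 and SMAD6 were detected on 2 of the 3 treated arrays and CCDC80 on 1. Their treated levels of 5.49, 5.26, 5.53 and 5.13 lay near the lowest values of detected probes on those arrays (5.25 to 5.45). The sizes of these falls are therefore limited by the detection floor.

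**Figure D1:**
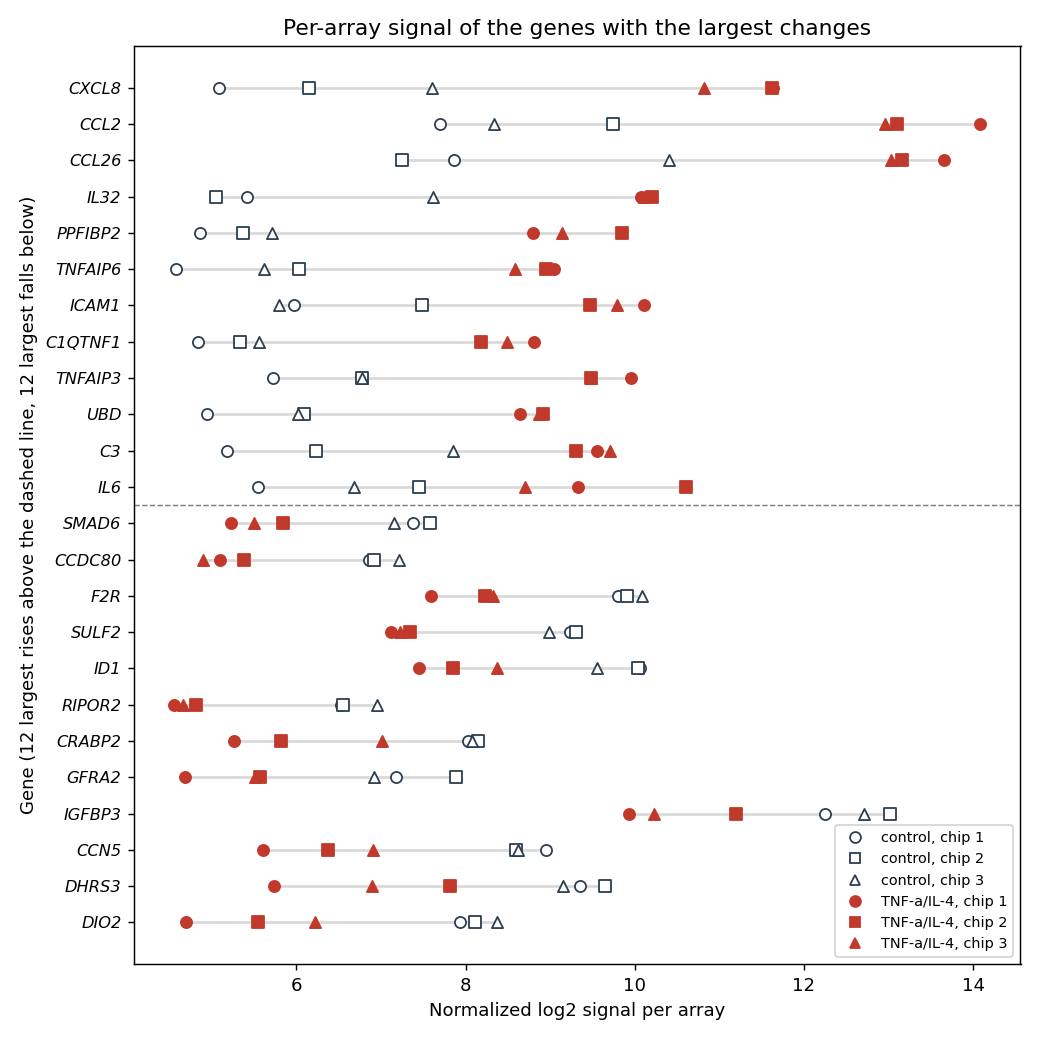
Normalized log2 signal on each array for the 12 genes with the largest rises and the 12 with the largest falls, open symbols for control and filled symbols for TNF-a/IL-4, the symbol shape giving the chip. The 3 arrays of a group do not overlap those of the other group for any of these genes, and the control values of CCL26 and CXCL8 spread more widely (SD 1.67 and 1.26) than their treated values (SD 0.33 and 0.47).

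Across all tested probes, 308 of 14659 passed the threshold, 160 higher and 148 lower with TNF-a/IL-4, and all 308 changed at least 1.5-fold. Read per gene, 269 of 10967 genes passed, 145 higher and 124 lower. Of these, 39 were higher and 6 lower by at least 4-fold, bounds standing for genes not detected in a group. The groups did not overlap for any of the 308 called probes, so each necessarily changed in the same direction on all 3 chips. Of all tested probes, 48.0% did so, where chance gives 25%. The groups did not overlap for 2817 probes (19.2%, against 10% by chance). With the chip as a block, 932 probes passed, 434 higher and 498 lower, of which 867 changed at least 1.5-fold, and 791 genes passed, and all 308 probes called without the block were among the 932. In fits chosen after seeing the data, the count with the block was 2368 with median scaling, 346 higher and 2022 lower. On the authors' values floored at 16 it was 0 by limma (3147 at an unadjusted p under 0.05). The count depends on the arrays: it was 120 (82 higher, 38 lower), 87 (70 and 17) and 155 (112 and 43) without control replicates 1, 2 and 3, and 170 (91 and 79), 87 (55 and 32) and 272 (118 and 154) without TNF-a/IL-4 replicates 1, 2 and 3. Among the called genes named below, IFIT3, PPM1D, SERPINE2 and MT2A missed the threshold in each of the 6 fits without a single array, PDCD1LG2, CDKN1C, COL6A2, ADAMTS1, HSPA5, NDRG1 and RIGI in 5, and PSMB10, GADD45A, LOX and ITGB4 in 4.

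Of the 29 measured NF-kB target genes, 11 rose, 1 fell and 17 did not pass. The largest rises after ICAM1 and TNFAIP3 were those of TNFAIP2 at 2.74 ± 0.41 and the mitochondrial superoxide dismutase SOD2 at 2.71 ± 0.42. GADD45B, a stress-response gene, fell by 1.13 ± 0.23 (adjusted p = 0.0402). Adjusted over the list alone, 22 rose and 1 fell, and with the block 20 rose and 1 fell over all genes. The list lay above other genes with a median log2 change of 1.11 (camera adjusted p = 4.96e-18), and its median was 1.41, 1.09 and 0.87 on chips 1, 2 and 3. The adjusted p was 0.0694 with an estimated correlation. NFKBIA, the inhibitor that retains NF-kB in the cytoplasm, differed by 2.24 ± 0.56 and missed the threshold (adjusted p = 0.0915), which it passed with the block (adjusted p = 0.0277). Its level was 9.44, 10.29 and 12.12 on control replicates 1, 2 and 3, and its difference was 3.12, 2.68 and 0.93 on chips 1, 2 and 3.

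Among 14 measured chemokines, 6 rose and 8 did not pass. After CXCL8, CCL2 and CCL26, the largest was CXCL1, another neutrophil chemoattractant, at 2.88 ± 0.43 (adjusted p = 0.0133). The T-cell chemoattractant CCL5 differed by 0.27 ± 0.32 (adjusted p = 0.835). 6 rose when adjusted over the list alone. The list's median change was 0.80 (adjusted p = 2.50e-07, and adjusted p = 0.0694 with an estimated correlation), and 1.15, 0.98 and 0.68 on chips 1, 2 and 3. Of 22 cytokines and growth factors, 5 rose, among them IL32, IL6, IL1B at 2.95 ± 0.41 and IL1A at 2.34 ± 0.34. In all, 10 rose adjusted over the list alone, and with the block 9 rose over all genes. The median was 0.46 (adjusted p = 4.03e-06, and adjusted p = 0.0694 with an estimated correlation), and 0.46, 0.60 and 0.46 on the 3 chips.

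Among 14 measured IL-4/STAT6 response genes, 5 rose and 9 did not pass. Besides CCL26, the suppressors of cytokine signalling SOCS1 and CISH were not detected on any control array and were at least 3.90-fold and at least 1.87-fold higher (adjusted p = 0.00308 and 0.0184). PDCD1LG2, the immune checkpoint ligand PD-L2, rose by 1.34 ± 0.25 (adjusted p = 0.0308). With p adjusted over the list alone, 8 rose, as did 8 over all genes with the block. The list's median change was 0.95 (adjusted p = 1.36e-07, and adjusted p = 0.0694 with an estimated correlation), and 1.12, 0.98 and 0.61 on the 3 chips. IL4R, the IL-4 receptor alpha chain, differed by 0.85 ± 0.20 and passed only with the block (adjusted p = 0.0721 without it and 0.0212 with it). STAT6 itself differed by 0.50 ± 0.18 (adjusted p = 0.251), and IL13RA1, the other chain of the type II receptor, by -0.44 ± 0.19 (adjusted p = 0.364).

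Of 34 cytokine receptor and JAK-STAT genes, 6 rose and 28 did not pass. The costimulatory receptor TNFRSF9 rose by 2.45 ± 0.24 and IL27RA by 1.23 ± 0.17, beside SOCS1 and CISH. Adjusted over the list alone, 10 rose, and with the block 9 rose and 1 fell. The median was 0.20 (adjusted p = 7.01e-05, and adjusted p = 0.0694 with an estimated correlation), and 0.31, 0.48 and 0.17 on the 3 chips. Of 12 leukocyte adhesion and costimulation genes, 2 rose, ICAM1 and PDCD1LG2, and 2 rose adjusted over the list alone. Their median was 0.23 (adjusted p = 0.00754, and adjusted p = 0.151 with an estimated correlation), and 0.32, 0.16 and 0.21 on the chips, and the call was lost without both arrays of replicate 1 (adjusted p = 0.134). The adhesion receptor VCAM1 differed by 1.12 ± 0.37 and passed only with the block (adjusted p = 0.216 without it and 0.0104 with it). The TNF receptor TNFRSF1A differed by -0.34 ± 0.18 (adjusted p = 0.515). The probes of TNF, IL2RG, TNFRSF1B and CCL11 did not pass the detection filter and were not tested.

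Some genes of antiviral defence and antigen presentation rose. Among 43 interferon-stimulated genes, 7 rose and 36 did not pass. XAF1, not detected on any control array, was at least 3.05-fold higher (adjusted p = 0.00767). The exonuclease ISG20 rose by 1.80 ± 0.20, the guanylate-binding protein GBP4 by 1.76 ± 0.28 and IFIT3 by 1.57 ± 0.31. A second, dimmer IFIT3 probe differed by 0.24 ± 0.24 (adjusted p = 0.787). 16 rose and 3 fell when adjusted over the list alone, and with the block 13 rose and 2 fell. The median was 0.39 (adjusted p = 2.59e-07, and adjusted p = 0.0694 with an estimated correlation), and 0.54, 0.36 and 0.31 on the chips. Of 18 genes of MHC class I presentation, 3 rose: the immunoproteasome subunit PSMB9 by 1.36 ± 0.21, the peptide transporter TAP1 by 1.25 ± 0.19 and the immunoproteasome subunit PSMB10 by 1.10 ± 0.18. In all, 8 rose adjusted over the list alone, and with the block 9 rose. The median was 0.58 (adjusted p = 1.52e-10, and adjusted p = 0.0694 with an estimated correlation), and 0.81, 0.55 and 0.57 on the chips.

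Of 16 complement and acute-phase genes, 4 rose: C3, the pattern-binding protein PTX3 by 2.57 ± 0.32, complement factor B (CFB) by 2.08 ± 0.25 and the protease inhibitor SERPINA1 by 1.93 ± 0.17. With p adjusted over the list alone, 6 rose and 1 fell, and with the block 6 rose and 1 fell over all genes. The median was 0.20 (adjusted p = 0.00144, and adjusted p = 0.0694 with an estimated correlation), and 0.08, 0.27 and 0.31 on the chips. Among 29 apoptosis and death receptor genes, 2 rose, the kinase RIPK2 by 1.49 ± 0.18 and the adaptor TRAF1 by 1.11 ± 0.17. Adjusted over the list alone, 9 rose and 1 fell, and with the block 6 rose and 2 fell. The median was 0.18 (adjusted p = 0.000577, and adjusted p = 0.0694 with an estimated correlation), and 0.25, 0.05 and 0.27 on the chips.

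Among 27 heat shock and unfolded protein response genes, 1 rose, the endoplasmic reticulum chaperone HSPA5 by 1.21 ± 0.21 (adjusted p = 0.0248). Asparagine synthetase (ASNS) differed by 1.12 ± 0.27 and passed only with the block (adjusted p = 0.0811 without it and 0.00734 with it). 4 rose when adjusted over the list alone, and with the block 8 rose. The median was 0.38 (adjusted p = 7.01e-05, and adjusted p = 0.0746 with an estimated correlation), and 0.49, 0.40 and 0.20 on the chips. Of 12 prostanoid and leukotriene genes, 2 rose, ALOX5AP, the 5-lipoxygenase activating protein, by 1.86 ± 0.24 and the phospholipase PLA2G4C by 1.35 ± 0.19. In all, 4 rose and 1 fell adjusted over the list alone, and with the block 3 rose. The list's median was 0.31 (adjusted p = 0.0317, and adjusted p = 0.151 with an estimated correlation), and 0.32, 0.29 and 0.01 on the chips. It missed the threshold with the block (adjusted p = 0.0913), without control replicate 1 (0.0883), without TNF-a/IL-4 replicate 1 (0.184) and without both arrays of replicate 1 (0.359).

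The lists that lay below other genes moved little. Of 16 cyclin-dependent kinase inhibitors and p53 targets, 1 rose and 2 fell. The growth arrest gene GADD45A rose by 1.61 ± 0.30, the kinase inhibitor CDKN1C fell by 1.33 ± 0.27 and the phosphatase PPM1D fell by 0.77 ± 0.16. CDKN1C was detected on 2 of the 3 treated arrays. With p adjusted over the list alone, 1 rose and 4 fell. The median was -0.27 (adjusted p = 0.00527, and adjusted p = 0.162 with an estimated correlation), and -0.45, -0.15 and -0.18 on the chips, and the call was lost without both arrays of replicate 1 (adjusted p = 0.125). Of 30 hypoxia and glycolysis genes, 1 fell, NDRG1 (2.83-fold lower, adjusted p = 0.0319). The lipase inhibitor ANGPTL4 differed by -0.91 ± 0.23 and passed only with the block (adjusted p = 0.0931 without it and 0.0205 with it). ANGPTL4 was detected on 1 of the 3 treated arrays. Adjusted over the list alone, 3 fell, and 3 fell with the block. The median was -0.16 (adjusted p = 0.0164, and adjusted p = 0.363 with an estimated correlation), and -0.26, -0.15 and -0.08 on the chips. The call was lost without TNF-a/IL-4 replicate 1 (adjusted p = 0.178), without both arrays of replicate 1 (0.146) and without both of replicate 2 (0.0933). Fry, an alternative list test, did not call it either (adjusted p = 0.0958).

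None of 48 cell cycle and DNA replication genes passed limma's test over all genes or adjusted over the list alone, and at an unadjusted p under 0.05 there were 1 higher and 5 lower. The replication helicase subunit MCM6 differed by -0.77 ± 0.20 and passed with the block (adjusted p = 0.111 without it and 0.0356 with it). Cyclin B1 (CCNB1) differed by -0.63 ± 0.25 (adjusted p = 0.326). The list's median was -0.08 (adjusted p = 0.0274, and adjusted p = 0.277 with an estimated correlation), and -0.20, -0.12 and 0.01 on the chips. The call was lost without control replicate 1 (adjusted p = 0.128), without TNF-a/IL-4 replicate 1 (adjusted p = 0.0620) and without both arrays of replicate 1 (adjusted p = 0.161).

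**Figure D2:**
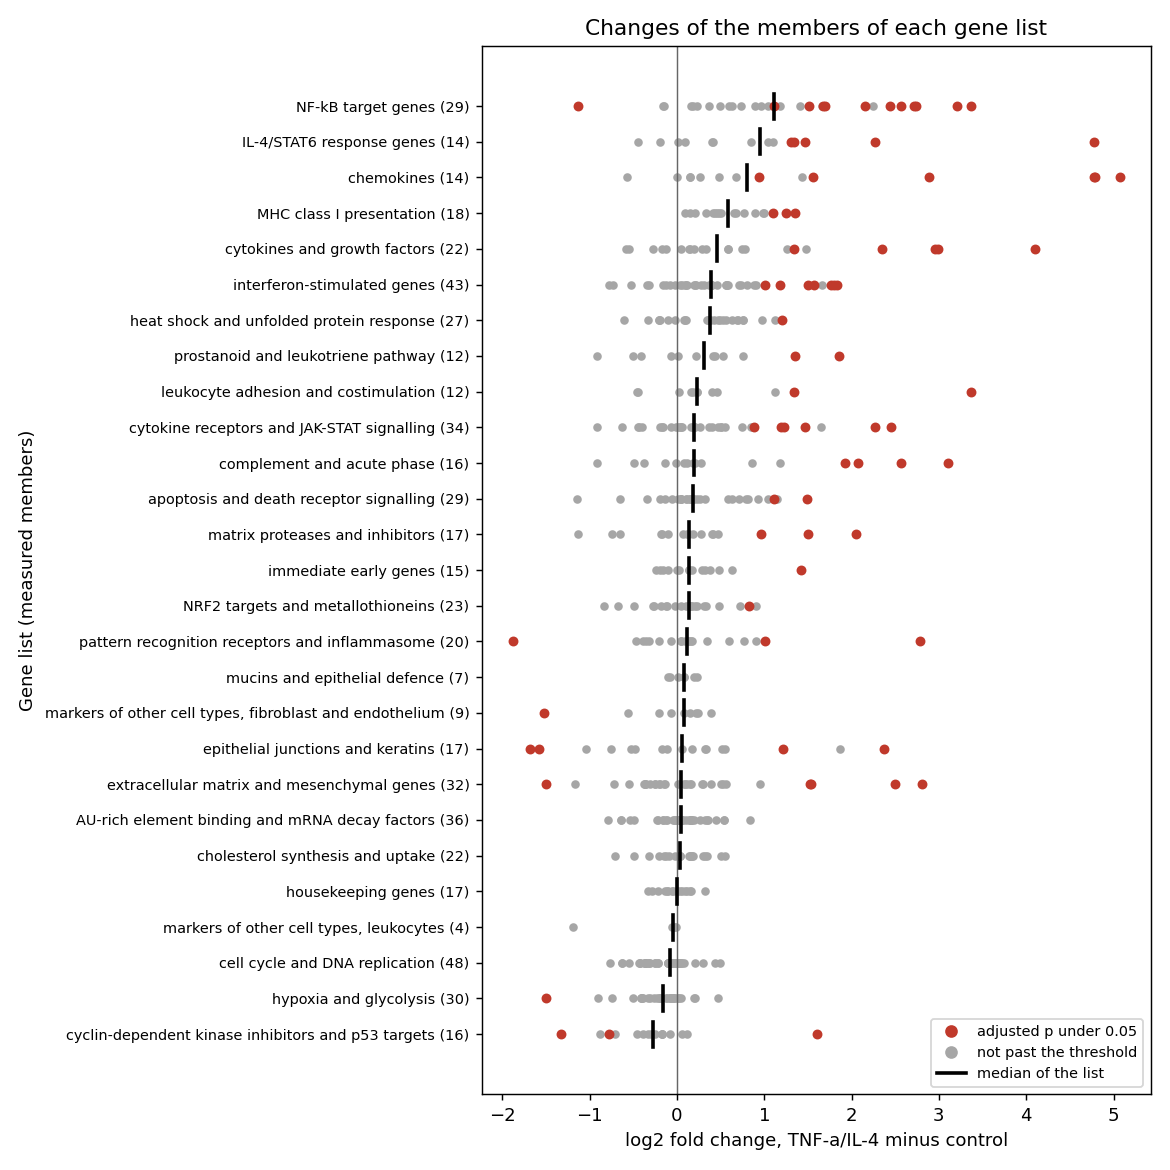
Log2 change, TNF-a/IL-4 minus control, of each measured member of 27 gene lists, with members past the threshold in red, the others in grey and the list's median as a black bar. The NF-kB target genes have the highest median (1.11), the housekeeping genes lie around 0, and the epithelial junction genes have called members on both sides.

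Camera did not call the remaining lists. Of 32 extracellular matrix and mesenchymal genes, 4 rose and 1 fell: COL6A1 rose by 2.81 ± 0.42, tenascin C (TNC) by 2.50 ± 0.31, COL6A2 by 1.53 ± 0.30 and the crosslinking enzyme LOX by 1.52 ± 0.27, and the transcription factor SNAI1 fell (2.84-fold lower, adjusted p = 0.00842). A second COL6A2 probe differed by 0.73 ± 0.23 (adjusted p = 0.194). 5 rose and 1 fell when adjusted over the list alone, and with the block 5 rose and 3 fell, and the median was 0.05 (camera adjusted p = 0.380). Of 17 matrix proteases and inhibitors, 3 rose: MMP9, not detected on any control array, was at least 2.83-fold higher, ADAMTS1 rose 2.83-fold (adjusted p = 0.0225) and SERPINE2 by 0.96 ± 0.18. In all, 3 rose and 2 fell adjusted over the list alone, and with the block 3 rose and 1 fell (camera adjusted p = 0.0929). Fry called this list higher (adjusted p = 0.0198). Among 17 epithelial junction and keratin genes, 2 rose and 2 fell, the tight junction protein CLDN1 rising by 2.37 ± 0.34 and the connexin GJB2 by 1.22 ± 0.18, while the hemidesmosome integrin ITGB4 fell by 1.69 ± 0.28 and the keratin KRT80 fell by 1.58 ± 0.22. With p adjusted over the list alone, 3 rose and 5 fell, with the block 4 rose and 3 fell (camera adjusted p = 0.974).

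Of 20 genes of the pattern recognition list, 2 rose and 1 fell. The receptor-proximal kinase IRAK2 rose by 2.79 ± 0.23 and the RNA sensor RIGI by 1.01 ± 0.20. The member that fell was F2R, the thrombin receptor, which the list also held. Adjusted over the list alone, 4 rose and 1 fell, with the block 5 rose and 1 fell (camera adjusted p = 0.203). Among 15 immediate early genes, the AP-1 subunit FOSL1 rose by 1.42 ± 0.21 and ATF3 differed by 0.63 ± 0.22 (adjusted p = 0.241), 1 rose adjusted over the list alone, and the list missed the threshold (camera adjusted p = 0.0610), which it passed without control replicate 2 (0.0251), TNF-a/IL-4 replicate 1 (0.0367), TNF-a/IL-4 replicate 3 (0.00370) or both arrays of replicate 3 (0.00494). Among 23 NRF2 target and metallothionein genes, MT2A rose by 0.82 ± 0.17, and MT1G at 0.90 ± 0.28 and AKR1C3 at -0.84 ± 0.20 passed only with the block (adjusted p = 0.190 and 0.0758 without it, 0.0336 and 0.0305 with it). 2 rose and 1 fell when adjusted over the list alone, and with the block 3 rose and 2 fell (camera adjusted p = 0.380).

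None of 36 AU-rich element binding and mRNA decay factors passed limma's test over all genes or adjusted over the list alone, with 3 higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.586). The RNase ZC3H12A differed by 0.84 ± 0.20 and the deadenylase CNOT8 by -0.78 ± 0.22, both passing only with the block (adjusted p = 0.0782 and 0.146 without it, 0.0433 and 0.0222 with it). The AU-rich element binding proteins ELAVL1 and ZFP36 differed by -0.00 ± 0.18 and -0.54 ± 0.29 (adjusted p = 0.996 and 0.511). None of 22 cholesterol genes passed over all genes or adjusted over the list alone, with 2 higher and 0 lower at an unadjusted p under 0.05 (camera adjusted p = 0.404), the largest differences being those of MSMO1 at -0.71 ± 0.39 and DHCR7 at 0.55 ± 0.18. None of 7 mucin and epithelial defence genes passed, by either adjustment or at an unadjusted p under 0.05 (camera adjusted p = 0.702). DEFB103A differed by 0.23 ± 0.21 and DUOX1 by 0.19 ± 0.29.

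Most markers of other cell types had no named probe that passed the detection filter. A marker without a named probe on the array was not told apart from an undetected one. Of 25 leukocyte markers 4 were measured, and none passed over all genes, with 1 lower at an unadjusted p under 0.05 and adjusted over the list alone. That was CPA3 at -1.19 ± 0.29, which passed with the block (adjusted p = 0.0876 without it and 0.00929 with it), and CORO1A differed by -0.06 ± 0.20. Of 20 fibroblast and endothelial markers 9 were measured, and 1 fell, PDGFRB by 1.53 ± 0.22 (adjusted p = 0.0107), as it did adjusted over the list alone, while S100A4 differed by -0.56 ± 0.31. Camera gave adjusted p = 0.336 and 0.702 for these lists, and fry called the leukocyte markers lower (adjusted p = 0.0311). None of the 17 markers of differentiated airway cells had a named probe that passed the detection filter, which does not show that they were not expressed. None of 17 housekeeping genes passed by either adjustment or at an unadjusted p under 0.05 (median 0.00, camera adjusted p = 0.702), with RPL13A at -0.33 ± 0.19 and TFRC at 0.32 ± 0.27.

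The arrays resembled each other by chip as much as by treatment. Pearson correlations of normalized values over 14659 probes averaged 0.977 between arrays of the same group (0.965 to 0.985), 0.975 between the 2 arrays of a chip (0.973 to 0.979) and 0.963 between arrays that shared neither (0.954 to 0.973).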

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

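Leaving out both arrays of a chip, and the combinations of the replicate block with median scaling, the authors' values or an estimated correlation, were chosen after seeing the data. No named called gene changed sign under any alternative run for genes, and no list was called in the other direction under those run for lists, which left out the other background corrections, cyclic loess, the filters, the spread model and array weights. All named called genes kept their call with the replicate block, whose counts were 932 probes, 867 at 1.5-fold and 791 genes, with 14 lists. Array weights gave 761 probes, 755 and 651, weighting control and TNF-a/IL-4 replicate 2 highest (2.61 and 2.19). Median scaling gave 148 probes, 148 and 128 genes, and moved the median of all tested probes to -0.15. The authors' values, floored at 16, gave 152, 152 and 126, and no filter, which tests 48701 probes, gave 156, 156 and 133. Why these counts differ was not tested. With the block, median scaling gave 2368 probes, 346 higher and 2022 lower against 434 and 498, and the authors' values gave 0 by limma (3147 at an unadjusted p under 0.05). Other processing gave 338 to 402 probes. Leaving out single arrays gave 87 to 272 probes, 87 to 272 at 1.5-fold, 71 to 232 genes and 13 to 16 lists. Leaving out a chip gave 33, 4 and 109 probes and 32, 4 and 97 genes without replicates 1, 2 and 3, and 10 to 16 lists, with fewer samples. The 4 genes called without replicate 2 were CCL2, ICAM1, PPFIBP2 and C1QTNF1. Of 69 named called genes, 29 passed without each array in turn.

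Of the 15 list calls, 0 held with an estimated correlation (10 at an unadjusted p under 0.05) and 0 with the replicate block as well (3). The estimates for the cytokine, complement and apoptosis lists, -0.011, -0.043 and -0.009, lay below the preset 0.01. A higher correlation is therefore not why those lists lost their calls. With an estimated correlation camera takes its degrees of freedom from the 6 arrays, so the losses alone do not show that list members vary together. Fry, which asks only whether a list moves, called 16. The immediate early genes and the pattern recognition genes passed with median scaling (adjusted p = 0.0353 and 0.0300), the complement and acute-phase list had a median of -0.02 there and stayed called as higher than other genes, and the prostanoid list was lost without background correction (0.136). The block changed no list call other than the prostanoid list. The mean correlation of same-chip deviations, 0.55, was 0.40 with no filter. Small changes are mostly missed: at 1 log2 unit the fit without the block recovered 19.4% of simulated changes.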

Other observations

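All tests of gene groups in the next 2 paragraphs use lists written after the called genes were seen, each tested only on members not seen before, and the test of mixed RNA and those of falls picked without normalization and of the detection limit were chosen after their patterns were seen.

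Ribosome biogenesis and amino acid genes were tested as groups after single members had been seen to rise. Of 31 ribosome biogenesis factors not seen before, all 31 had a positive difference, with a median of 0.40 (camera adjusted p = 5.01e-09 over the 4 added lists, and adjusted p = 0.0559 with an estimated correlation). By limma's test, 9 were higher at an unadjusted p under 0.05, and 5 rose with the block. The median was 0.51, 0.42 and 0.28 on chips 1, 2 and 3, and 0.21 with median scaling. Of 26 amino acid response and tRNA synthetase genes, 19 had a positive difference, with a median of 0.27 (camera adjusted p = 0.00459, and adjusted p = 0.0895 with an estimated correlation). The median was 0.42, 0.32 and 0.18 on chips 1, 2 and 3, and 0.10 with median scaling. By limma's test, 9 were higher and 3 lower at an unadjusted p under 0.05, and 3 rose with the block. PYCR1, an enzyme of proline synthesis, differed by 0.75, while the amino acid transporters SLC38A2, SLC7A5 and SLC3A2 differed by -1.30, -0.66 and -0.54 and did not pass with the block.

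The fall of ID1, SMAD6 and BMP4 (-1.79, with another probe that did not pass) raised the hypothesis that targets and parts of BMP signalling are lower as a group. Of 11 members not seen before, 2 had a positive difference, and the median was -0.50 (camera adjusted p = 0.0419, and adjusted p = 0.116 with an estimated correlation). It was -0.37, -0.64 and -0.17 on chips 1, 2 and 3. By limma's test, 6 had an unadjusted p under 0.05, of which 1, RUNX2, was higher. With the block 1 rose, RUNX2 at 0.74, and 1 fell, SMAD5 at -0.64. The members not seen before include inhibitors of the pathway, SMAD7, GREM1 and NOG at -0.67, -0.74 and -0.33 and BAMBI at 0.40. The shift of the list therefore does not tell whether BMP signalling was lower. The fall of DHRS3 and CRABP2 raised the same question for retinoid-regulated genes, of which CYP26B1 fell as well (at least 1.28-fold, undetected on the treated arrays), while RARRES1 (1.52) and TGM2 (1.30) rose, each with another probe that did not pass. The 11 members not seen before had a median of 0.02 (adjusted p = 0.636), PLAAT4 (1.11) and MEIS2 (0.84) rising and RARA (-0.72) falling with the block alone, which leaves the hypothesis open.

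The treated arrays were dimmer on each chip, so the falls could reflect lower sensitivity of those arrays. Before normalization between arrays, the dimmest 25% of the tested probes were lower on the treated arrays by a median of -0.09 and all tested probes by -0.18. The smallest fall among the 148 lower calls was -0.77 ± 0.16 (SE), that of PPM1D. The call threshold sets that size, so it decides nothing. Of 106 probes called lower in a fit without normalization between arrays, 85 were also called after it. The median change of the 106 went from -1.53 to -1.32 ± 0.04 (bootstrap SE). These probes were picked for their fall, and removing a median difference of -0.18 could not undo it. The values therefore show only that normalization removed little of these falls, and they do not test brightness as their source. The 98 lower calls detected on all 3 treated arrays had treated levels a median of 1.80 ± 0.18 (bootstrap SE) log2 units above the highest detection limit of an array. In 69 of them the treated mean lay more than 1 unit above that limit, and in 29 it did not. The 98 were chosen by detection and the other 50 lower calls were left out. The median therefore decides nothing about a loss of signal near the limit. For the 69, treated means that far above the limit argue against such a loss. It stays open for the 29 and for the other 50. A response to the cytokines stays open for all the lower calls. Chip position follows treatment on all 3 chips and cannot be told apart from it.

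Both arrays of a chip deviated together from their group means. Overall brightness of the chip is a possible source, and a smooth function of probe brightness explained at most 0.00957 of the variance of the chip deviations after normalization. Before normalization it explained up to 0.142, on chip 3, above the bound of 0.1 set for excluding it, so brightness is not excluded. Cultures grown and hybridized together would give the same pattern, and no label tells these apart.

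On control replicate 3, CCL26, IL32, C3 and CXCL8 lay well above the other control arrays. If RNA of the treated array of that chip had been mixed in, these genes would need a share of 14.2%, 14.7%, 22.3% and 8.10% on the linear scale. The other 141 genes that rose implied a median share of 8.89% ± 2.25 (bootstrap SE), and 69 of them lay below the 8.10% of CXCL8. The median was close to the share of CXCL8 and below those of CCL26, IL32 and C3. Whether mixing accounts for part of the pattern stays open. Single genes disagree with a common share: ICAM1 gave -8.55% and CCL2 gave -2.81%. A culture with a higher resting level of these genes would predict a similar median, and no biological explanation was tested.

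The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real grouping gave 308 probes, 308 at 1.5-fold, 269 genes and 15 lists, and in each case 1 of the 10 splits, the real one, gave as many. The highest of the other splits was 0 probes (1557 at an unadjusted p under 0.05 against 1850), 0 at 1.5-fold, 0 genes and 13 lists. Every other split mixes the treatments in unequal numbers, so it still carries part of the treatment difference and its counts are not those of a comparison without treatment. The split with 1557 keeps both arrays of chip 1 in the same group and so carries the chip deviations, which a fit without the block leaves in. The 3 other splits that part the arrays of all 3 chips, as the real one does, gave 125, 51 and 85 probes at an unadjusted p under 0.05, and 1 of them gave the 13 lists.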
